A study of Mus musculus with 10 samples.

How the data were processed

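RNA sequencing was done on 10 mouse samples, 4 labelled CM and 6 labelled control. The submitters' processing notes name bcl2fastq 2.18.0.12, TopHat2 and the mm10 build, without giving their role or order. The counting tool, the annotation and the filters are not given in the sources used here. The authors deposited 2 tables of 25078 gene rows each, named by them as raw counts and as RPKM. Gene positions and other annotation, such as the summed length of the exons, stood beside the values. Only the annotation of the raw count table was read, so the genes of both tables were not compared.

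Each table has 10 columns of values. The numbers in their headings were searched for in all labels and in the design text, and 0 were found. Columns were not assigned to samples from their order, from the prefix of their headings or from their values. The 20 value columns of the 2 tables were therefore not used in any step, and the tests, alternatives and gene list comparisons planned before the data were examined were not run. The planned comparison was unpaired, because the labels do not say that the same number in both groups marks a shared litter.

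The gene table was read with pandas 2.3.3 in Python 3.11.15. Each symbol was looked up in GENCODE M21, an annotation of mm10. A gene was taken as matched in place when the positions of both shared at least 1 base on the same chromosome and strand. The gene lists were matched by exact symbol, so a gene listed under a renamed symbol is not matched. As an alternative chosen after seeing the data, symbols were also matched through the synonyms of the RefSeq gene table of GRCm38. The 6 named genes are those that the rule written beforehand always names where counted. They are named here because they are listed, without reading their counts. The rest of the rule depends on test results and fold changes and was not applied.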

Results

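The study set out to compare gene expression in the bone marrow of CM mice that had reached the leukemic stage with that of control littermates. The labels give 10 mouse samples, of which 4 carry the CM genotype and 6 the control genotype. They do not spell out what CM stands for. The tissue label reads PBMC, the usual abbreviation for mononuclear cells of the peripheral blood, while the protocol and the design text describe mononuclear cells taken from crushed femurs, tibias and pelvic bones after lysis of red cells. The molecule was total RNA, and the protocol names a kit for mRNA libraries beside one for microRNA libraries.

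The comparison of CM with control marrow was not made here. Both tables head their 10 value columns with laboratory numbers, and 0 of those numbers stand in the title, description or any other label of a sample. A prefix divides the columns into 6 and 4, which equals the sizes of the groups. The prefix is not a label of genotype, however, and it can mark a laboratory batch as well as a group. Without a label that ties a column to an animal, no fold change, level, error or test of CM against control marrow is given. No depth can be tied to a labelled sample, and the depth of the unlabelled columns was not computed. No statement on which genes were higher or lower in leukemic marrow follows from what is reported here.

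What could be described without the sample columns was the set of genes listed in the tables. Whether a listed gene had any reads was not examined. The raw count table listed 25078 genes, each under a distinct symbol, with a position and the summed length of its exons. The median exon length was 2251 bases, with quartiles of 1126 and 3809 bases, and the extremes were 21 bases and the 104320 bases of Ttn, which encodes the giant muscle protein titin. Genes with fewer than 200 bases of exon made up 5.29% of the table (1326 genes). The symbols of 24290 genes (96.86%) stood in the GENCODE M21 annotation of mm10, and 24207 of those (99.66%) overlapped the annotated gene on the same chromosome and strand. Another 4 overlapped it on the opposite strand, and 79 did not overlap it. Symbols were compared exactly, so a gene that GENCODE lists under another symbol was counted as absent.

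Of the 602 distinct genes in the 30 lists fixed before the data were examined, 564 were matched in the table by exact symbol, and 27 lists were matched in full. A match shows only that the symbol is listed, not that the gene was detected. All 26 genes of blood stem and progenitor cells, all 16 genes of primary granules, all 21 genes of mature neutrophils, all 23 genes of monocytes and macrophages, all 27 B lineage genes and all 19 T lineage genes were matched. Of the 29 red cell genes 28 were matched, and the remaining gene was matched neither by symbol nor by synonym. Of the 13 protein-coding genes of the mitochondrial genome 0 were matched by symbol or synonym, and 0 of the genes read here lay on the mitochondrial sequence. The replication-dependent histone genes had been listed under older symbols, and 23 of the 24 were matched through a synonym.

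The 6 genes that were always to be named where counted were all listed in the table. Each overlapped its protein-coding GENCODE gene on the same strand of mm10. Whether they had counts in any sample was not examined. Kit, the receptor of stem cell factor, lay on chromosome 5 from 75574987 to 75656721, with 5181 bases of exon. Cd34, a surface protein of progenitor cells, lay on chromosome 1 from 194938821 to 194961292, with 2621 bases. Gata2, a transcription factor of stem and progenitor cells, lay on chromosome 6 from 88193891 to 88207032, with 3353 bases. Cbfb, the beta subunit of core binding factor, lay on chromosome 8 from 105170674 to 105217988, with 2913 bases. Runx1, an alpha subunit of the same complex, lay on the minus strand of chromosome 16 from 92601466 to 92826074, with 7378 bases. Myh11, which encodes the myosin heavy chain of smooth muscle, lay on the minus strand of chromosome 16 from 14194527 to 14291408, with 6632 bases.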

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

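The other normalizations, filters and tests chosen before the data were examined apply to sample values and were not run, because no column of values could be tied to a sample. No paired analysis was possible because the columns carry no replicate number. The settings below were chosen after seeing the data. Matching the list genes through RefSeq synonyms raised the matched genes from 564 to 587 of 602. The share of matched symbols that overlapped their GENCODE gene on the same strand was 99.66% with at least 1 shared base and 99.63% when unplaced scaffolds were added to the annotation. It was 90.14% when at least 50% of the longer of both gene models had to be shared. Sequence names were compared as written, so a scaffold named differently in the annotation could not match.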

Other observations

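Some genes of the table have start and end positions that lie far apart. The distance from start to end was at least 3 megabases for 24 genes, of which 20 lay on the Y chromosome. These were not all separate positions, because several of the genes shared their start and end with another of them. The widest, Mir3084-1, was given a span of 35.8 megabases on chromosome 19 with 135 bases of exon, and Mir3084-2 was given the same start, end and exon length. Sly, a multicopy gene of the Y chromosome, spanned 20008334 bases. Srsy and LOC115489290 shared the same start, end and exon length of 11326 bases. Whether such positions join several copies of a gene, and which copy the reads came from, was not examined here.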
